A study of Escherichia coli str. K-12 substr. MC4100 with 10 samples.

How the data were processed

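The series comprises 10 libraries of Escherichia coli MC4100, 5 of mRNA and 5 of ribosome-protected fragments (RPF), from 4 conditions. Per the labels' protocols, cells were chilled with chloramphenicol at harvest, ribosome-bound mRNA was digested with micrococcal nuclease to give RPFs, and the heat stress aliquot was centrifuged and resuspended before the heat, a step the labels do not give for LB. The numbers 1 and 2 of the LB cultures name the library without and the library with the words biological replicate in its title, and the labels do not say which mRNA and RPF libraries share a culture. They were paired by number, which is an assumption on which the fit with the culture as a block rests. The differences between the LB replicates had a Pearson's r of 0.284 between mRNA and RPF. The stretch of the chromosome described in the results was higher in replicate 2 in both, and its genes enter that r. Some lists differed between the replicates in the same direction, such as amino acid biosynthesis (0.45 in mRNA, 0.25 in RPF). Others differed in opposite directions, such as sulfate assimilation (1.97 and -1.21) and iron uptake (0.93 and -1.16).

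Each deposited file lists 4293 gene names with 1 value per gene, a signal made by the authors and not a count. No header or label says how it was made, and the aligner, the read counter, the genome build and the filters are not given in the sources used here. The unit was worked out from the values: the deposited signal times the gene length was a whole multiple of 1 step per library, so the value is the number of reads divided by the gene length and by a constant of the library. This constant lay between 67.0 and 180, close to the median number of reads per gene, so the values are not scaled to the library total, although the plan assumed RPKM. The lengths came from the RefSeq gene table of assembly ASM584v2 of strain MG1655, which was used only for names, lengths and the order of genes: 3543 names matched a current symbol, 614 an older name, and 136 did not match. With these lengths, 88.6% to 96.0% of the values of genes under 1000 reads came out within 0.02 of a whole number of reads, and 95.7% to 96.2% within 0.02 of a multiple of 0.5 reads. RPKM was then computed from the reads so recovered, and the planned test was applied to it. For names with no length, the deposited value was scaled by the same factor. Between 17 and 67 genes per library were listed at 0.

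Genes with a mean RPKM of at least 5 over the 10 libraries were tested (3938 genes). Values were taken as log2(RPKM + 1), and each library was shifted so that the median difference from the mean of the 10 libraries was 0. A linear model with 8 group means was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), which has 2 residual degrees of freedom, both from the LB cultures, and a prior of 2.48 degrees of freedom. The 11 contrasts are each stress against its medium and MM against LB, in mRNA, in RPF and in RPF relative to mRNA (translational efficiency, the interaction of the same model), and the heat response against the osmotic response. P-values were adjusted by Benjamini-Hochberg over the tested genes within a contrast, and a gene was called at an adjusted p under 0.05. The mapping of samples, these tests, the alternatives and 24 gene lists were fixed before the data were examined.

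For each list the number of genes past the test is given over all tested genes and adjusted over the list alone. A further test, limma on the mean log2 value of each list (24 lists, 8 groups, prior of 8.87 degrees of freedom, adjusted over the 24 lists), was added after the calls of single genes had been seen, and all list changes with an SE in the results come from it. It asks whether a list's mean differs between groups beyond the spread of list means between the LB cultures. With 2 residual degrees of freedom against the prior of 8.87, that spread is mostly pooled over the 24 lists and only in small part the list's own. Named genes follow a rule fixed beforehand: of each contrast the 8 largest rises and falls in mRNA and the 5 largest in RPF and in translational efficiency, passing genes first, from genes above 0 in all libraries compared, plus up to 4 members of a described list with the largest changes. Each list's median change was also set against 10000 random lists of the same size, matched on level in 20 bins, as planned; these percentiles are a description and are not printed. Near-identical copies such as gadA and gadB are named with that limit, since how the authors assigned shared reads is not given in the sources used here.

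The fit was tested on simulated reads for the comparison of heat stress with LB in mRNA, with 200 changed genes among 3840 in each of 20 simulations, and with the spread of a simulated gene limited to an SD of 2, a limit added after the first simulations. It called 3.66% of genes changed by 2 on the log2 scale, 46.19% of those changed by 4, 66.74% of those changed by 6 and 0.11% of unchanged genes. The list test was tried on simulated list means, not reads, drawn with 1 common SD for all 24 lists. It called 33.3% of list means shifted by 1, 96.7% of those shifted by 2 and 99.2% of those shifted by 3. Of the lists not shifted it called 0.28% to 3.06%. The real lists differ in spread: between the LB mRNA libraries cold shock differed by -0.06 and sulfate assimilation by 1.97. The shares called may therefore not hold for each real list. A gene or list with a smaller change will therefore often not pass.

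The alternatives were pseudocounts of 0.25 and 5, no filter and a minimum mean RPKM of 20, no rescaling, quantile normalization, a fit on one kind of library, a minimum log2 change of 1, each LB library left out, and the culture as a replicate block. Added after seeing the data were limma-voom on the recovered reads, the authors' own scaling, a term for the split of LB replicate 1 and heat stress from the other libraries, and a fit without the genes of the chromosome stretch, whose ends were set from the LB mRNA differences themselves. Where an LB library was left out, its lone partner was assumed to vary like the other pair. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.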

Results

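Messenger RNA and ribosome-protected fragments (RPF) were measured in Escherichia coli MC4100, a laboratory strain with a deletion of the argF-lac region of the chromosome. mRNA-Seq measures the abundance of each transcript. Ribosome profiling sequences the pieces of mRNA covered by ribosomes, so an RPF level depends on the transcript's abundance and on how densely ribosomes occupy it. The labels describe 4 conditions: mid-log growth in LB (a rich medium) at 37 °C, heat stress of LB cells for 7 min at 47 °C, mid-log growth in MM (a salts medium with ammonium and glucose), and osmotic stress of MM cells for 20 min with NaCl at 0.3 M. LB had 2 libraries of each kind, the second of each titled a biological replicate. They were taken as 2 cultures, with mRNA and RPF libraries paired by number, which the labels do not state. Heat stress, MM and osmotic stress had 1 library of each kind, giving 10 libraries in 8 groups. The design text sets transcriptional beside translational control, and the comparisons below follow it: each stress against its own medium, and MM against LB.

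The number of reads recovered per library ran from 2592561 (osmotic stress mRNA) to 7759736 (LB RPF replicate 1). The 10 most abundant genes held 41.4% of the reads of the heat stress RPF library, against 17.9% and 17.2% in the LB RPF libraries. Of the 4293 genes listed per library, 3938 had a mean RPKM of at least 5 and were tested. Changes are differences of log2(RPKM + 1), which understates the change of weakly expressed genes, after each library was shifted to a common median. These shifts ran from -0.41 (LB RPF replicate 1) to 0.63 (osmotic stress mRNA), so every change is relative to the median gene. Errors are standard errors of the limma fit. Heat stress, MM and osmotic stress have no replicate, and their libraries were assumed to vary as the LB libraries do; the p-values rest on the spread between those 2 LB cultures alone.

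The LB cultures differed from each other at many genes. Pearson's r across genes was 0.875 for mRNA and 0.920 for RPF, and the SD of the log2 difference was 1.24 and 1.05. At least 2-fold differences between the LB libraries were found at 1025 of the 3938 genes in mRNA and at 909 in RPF. These numbers were 1336 and 1642 for heat stress, 1048 and 1035 for osmotic stress and 1376 and 1491 for MM. The heat and MM numbers are against the mean of 2 LB libraries. Against LB replicate 1 and replicate 2 alone, heat stress gave 1347 and 1655 genes in mRNA and 1560 and 1902 in RPF. MM gave 1638 and 1309 in mRNA and 1738 and 1392 in RPF. Part of this difference lay in 1 stretch of the chromosome, the 372 tested genes from metA to the end of the reference gene order at yjtD. There, LB replicate 2 was higher than replicate 1 by a median of 1.46 in mRNA and 1.10 in RPF, on the log2 scale. The acid resistance, sulfate assimilation, respiratory chain and cold shock lists have 0 members in that stretch. The mRNA and RPF differences between the LB cultures had a Pearson's r of 0.284 across genes. Because of these differences a term that splits LB replicate 1 and heat stress from the other libraries, called the batch term below, was tried. Each list call was repeated under 13 alternative settings, the batch term among them. The batch term, or leaving out an LB library, leaves 1 residual degree of freedom instead of 2. Where either ended a call, the spread was pooled wholly over all lists, instead of mostly, and the SE was larger. The fit without the genes of the stretch lowers the prior degrees of freedom from 8.87 to 2.57. The changes are given with the lost calls, since a lost call alone does not show that a change came from a batch or from the stretch.

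**Figure D1:**
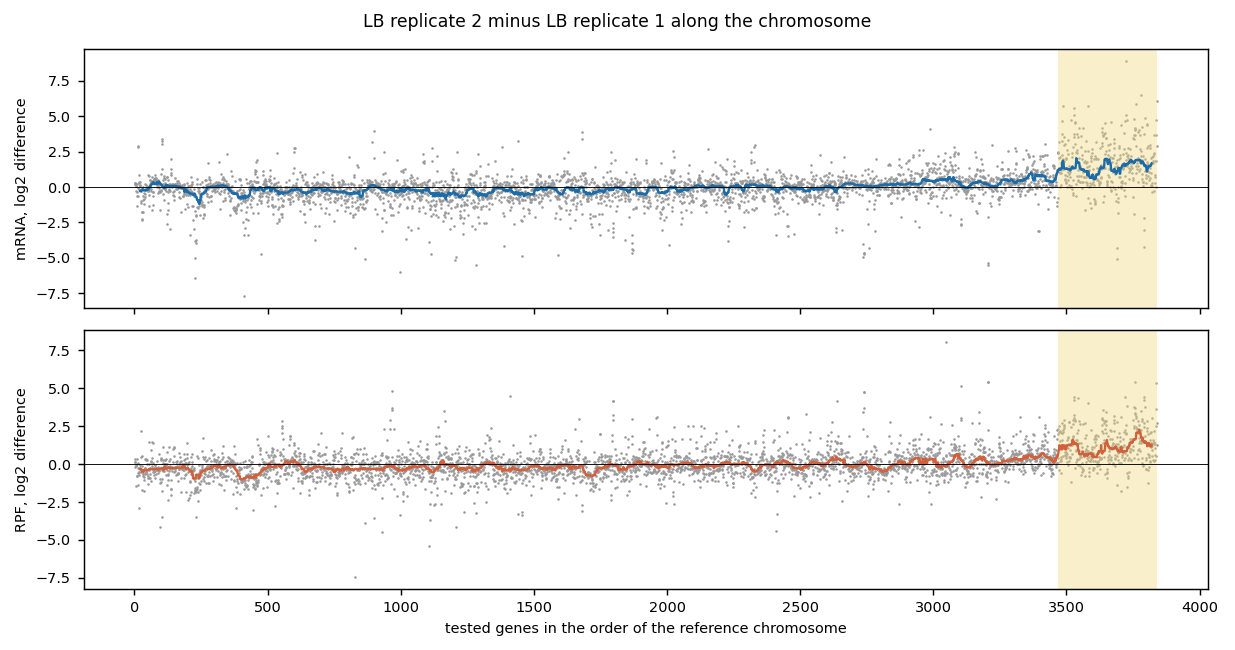
Log2 difference between LB replicate 2 and LB replicate 1 for each tested gene (grey points), in mRNA (top) and RPF (bottom), with genes in the order of the reference chromosome; the line is a running median over 41 genes. In the shaded stretch from metA to yjtD the median difference was 1.46 in mRNA and 1.10 in RPF, against -0.09 and -0.13 over the other genes.

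Heat stress raised the sigma32 regulon, the chaperones and proteases that refold or degrade damaged proteins. The mean mRNA change of its 28 tested genes was 3.07 ± 0.54 (SE, adjusted p = 0.00167), and the mean RPF change was 2.75 ± 0.54 (adjusted p = 0.00206), with all 28 genes higher in both kinds of library. Genes of energy metabolism moved the other way: the respiratory chain and ATP synthase list fell (-2.96 ± 0.41 in mRNA, adjusted p = 0.0004; -2.48 ± 0.41 in RPF, adjusted p = 0.00168), and the TCA cycle list fell (-2.69 ± 0.58 and -2.60 ± 0.58, adjusted p = 0.0056 and 0.00435). The sizes depend on the LB library used. Against LB replicate 1 and replicate 2 alone, the sigma32 change was 3.75 and 2.39 in mRNA and 2.71 and 2.78 in RPF. The TCA cycle change was -2.90 and -2.47 in mRNA and -1.84 and -3.36 in RPF, and 4 of its 19 genes lie in the stretch. Cold shock proteins, small RNA-binding proteins, fell by 2.31 ± 0.40 in RPF (adjusted p = 0.00168, all 7 genes lower).

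The largest sigma32 changes were those of the small heat shock proteins and the disaggregase. The gene ibpB went from 23.9 and 19.4 RPKM in the LB mRNA libraries to 5130 under heat stress (log2 change 7.43 ± 0.43), and its RPF rose by 5.86 ± 0.43. For ibpA the mRNA change was 6.30 ± 0.76, and for clpB, the disaggregase, it was 5.47 ± 0.79 in mRNA and 5.46 ± 0.79 in RPF. The chaperone gene dnaK reached 69600 RPKM in the heat stress RPF library, from 4440 and 3850 in LB, with an mRNA change of 4.25 ± 1.22. Of the 28 sigma32 genes, 25 passed in mRNA and 22 in RPF when p was adjusted over the list alone; over all tested genes, 0 passed in mRNA and 1 in RPF. Outside the list, yceP (bssS, a biofilm regulator) was higher by 4.99 ± 0.37 in mRNA and rose by 7.18 ± 0.37 in RPF. Further large mRNA differences that did not pass were those of ycfR (bhsA), 5.34 ± 0.78, yedR (drpB), 5.25 ± 0.73, and yjcB, 4.23 ± 0.83. The last, yjcB, lies in the stretch that differed between the LB cultures. Among envelope stress genes, the periplasmic protease gene degP was higher by 2.61 ± 0.51 in mRNA, and the periplasmic chaperone gene spy by 2.03 ± 0.42 in mRNA and 4.18 ± 0.42 in RPF, none of which passed.

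Among the respiratory genes, cyoA and cyoB, subunits of the cytochrome bo oxidase, had mRNA changes of -5.50 ± 0.30 and -5.08 ± 0.33 and fell in RPF (-4.80 ± 0.30 and -4.62 ± 0.33). The complex I genes nuoM and nuoG had mRNA changes of -4.73 ± 0.42 and -4.42 ± 0.42. Adjusted over the list alone, 26 of the 29 respiratory genes passed as lower in mRNA and 25 in RPF, against 0 and 3 over all tested genes. In the TCA cycle list, sdhD and sdhA, subunits of succinate dehydrogenase, had mRNA changes of -5.07 ± 1.16 and -4.88 ± 1.04. The list of uptake systems for other carbon sources fell (-2.60 ± 0.62 in mRNA, -3.25 ± 0.62 in RPF, adjusted p = 0.0072 and 0.00206, 30 of 32 genes lower in both). Its members rbsC, rbsB, malE and malK, parts of the ribose and maltose transporters, had mRNA changes of -5.32 ± 0.75, -4.91 ± 0.92, -5.18 ± 1.15 and -4.94 ± 1.89. Of its 32 tested genes, 8 lie in the stretch that differed between the LB cultures, malE and malK among them. Without the genes of the stretch the list's change was -2.33 ± 0.78 in mRNA and -2.52 ± 0.78 in RPF and no longer passed (adjusted p = 0.104 and 0.0918). The mRNA call was also lost at a mean RPKM of at least 20 (-2.66 ± 0.75, adjusted p = 0.0552) and with quantile normalization (-2.66 ± 0.67, 0.0537). Glycolysis genes fell (-1.75 ± 0.40 in mRNA, -1.73 ± 0.40 in RPF, 17 and 15 of 17 genes lower), and fbaA, the aldolase gene, fell by 3.84 ± 0.28 in RPF. The manganese superoxide dismutase gene sodA fell by 5.67 ± 0.34 in RPF, and cyoD fell by 4.13 ± 0.31. The porin gene nmpC had an mRNA change of -5.15 ± 0.54. Of the cold shock list, cspE and cspC had RPF changes of -4.90 ± 0.41 and -3.70 ± 0.57.

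By limma, 0 of the 3938 genes passed in mRNA, with 647 at an unadjusted p under 0.05, and limma-voom on the recovered reads also called 0. Other settings called some: 2 with a pseudocount of 5, 18 with no filter on low values, 11 with quantile normalization (3 higher, 8 lower), 10 with the authors' scaling and 47 without the genes of the stretch (14 higher, 33 lower). In RPF, 7 genes passed, 2 higher and 5 lower, all at an adjusted p of 0.0482. With no rescaling the RPF count was 1, higher, with quantile normalization 3, 1 higher and 2 lower, with a pseudocount of 5 or the batch term 0, and without the genes of the stretch 165, 55 higher and 110 lower. Leaving out each LB library in turn gave 0 to 8 mRNA calls and 0 to 14 RPF calls, above 0 only without LB mRNA replicate 2. Among the lists, the outer membrane porin falls (-1.43 ± 0.42 in mRNA, -1.37 ± 0.42 in RPF), the cold shock fall in mRNA (-1.43 ± 0.40) and the acid resistance rise in RPF (1.23 ± 0.41) were each lost without any 1 of the 4 LB libraries, with adjusted p from 0.0631 to 0.325. The changes then ran from -1.24 to -1.63, -1.22 to -1.56, -1.40 to -1.48 and 1.04 to 1.37, with SEs of 0.56 to 0.67, and the calls were kept in 4, 5, 5 and 3 of the 13 settings. The glycolysis call was lost in mRNA without either LB mRNA library and in RPF without LB RPF replicate 2, with adjusted p up to 0.095 and 0.0616, and with the batch term (-1.67 ± 0.74 and -1.66 ± 0.74, adjusted p = 0.159 and 0.14). The TCA cycle calls were lost at a mean RPKM of at least 20 (-2.44 ± 0.64 and -2.20 ± 0.64, adjusted p = 0.0552 and 0.0546).

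**Figure D2:**
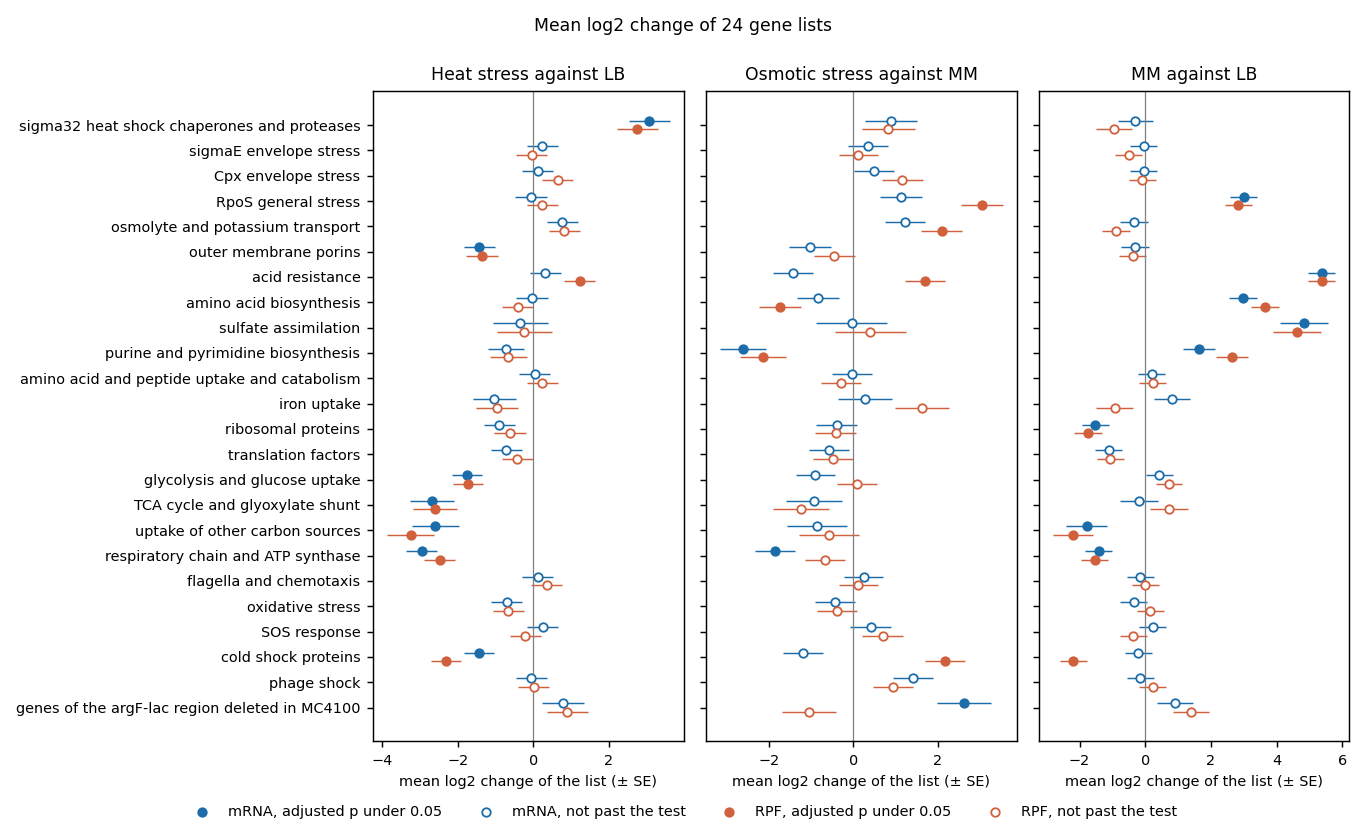
Mean log2 change of each of the 24 gene lists in mRNA (blue) and RPF (orange) for heat stress against LB, osmotic stress against MM and MM against LB; bars are standard errors and filled points passed at an adjusted p under 0.05. The sigma32 list rose by 3.07 in mRNA under heat stress, the RpoS list by 3.04 in RPF under osmotic stress and the acid resistance list by 5.37 in mRNA in MM.

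Osmotic stress raised the RPF of the RpoS regulon, the genes of the general stress response. Its 29 genes were all higher in RPF, with a mean change of 3.04 ± 0.49 (adjusted p = 0.00156), while the mean mRNA change was 1.13 ± 0.49 and did not pass (adjusted p = 0.12). The change in RPF relative to mRNA, 1.91 ± 0.69, did not pass either (adjusted p = 0.109). Genes for osmolyte and potassium transport rose by 2.09 ± 0.48 in RPF (adjusted p = 0.00939), and cold shock proteins by 2.16 ± 0.47 (adjusted p = 0.00881), from a mean level of 8.59 in MM to 10.75, against 10.90 and 10.67 in LB. Genes of purine and pyrimidine biosynthesis fell (-2.61 ± 0.55 in mRNA, -2.14 ± 0.55 in RPF, adjusted p = 0.0155 and 0.0159), and amino acid biosynthesis genes fell by 1.74 ± 0.49 in RPF (adjusted p = 0.0177, 70 of 73 genes lower).

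Only 2 genes passed over all tested genes, both in RPF: ymdF rose by 7.78 ± 0.41, from 95.6 to 16800 RPKM, and yjbJ by 7.25 ± 0.33, from 164 to 19900 RPKM. The gene yjbJ lies in the stretch that differed between the LB cultures. In the RpoS list 24 genes passed in RPF when p was adjusted over the list alone, against 1 over all tested genes, and 6 and 0 in mRNA. Its member ygdI was higher in RPF by 6.04 ± 0.49, yhbO by 5.81 ± 0.54, and otsB, which makes trehalose, by 4.79 ± 0.89. The gene osmY, for a periplasmic protein, had an mRNA change of 2.66 ± 0.44. The glycine betaine transporter genes proV, proW and proX had large mRNA differences: proV went from 44.4 to 3140 RPKM, and proW and proX were higher by 5.54 ± 0.82 and 5.73 ± 0.43, with RPF differences of 5.47 ± 0.55, 4.92 ± 0.82 and 5.66 ± 0.43. Among the osmolyte transport genes, 5 passed in RPF when adjusted over the list alone and 0 over all tested genes. The genes yciE, yciF, yciG, ymgA and ymgB (ariR) were higher in mRNA by 4.60 ± 0.77, 4.73 ± 0.91, 4.41 ± 1.25, 4.36 ± 0.42 and 4.56 ± 0.90. In RPF, bdm, ybgS and yciF were higher by 7.29 ± 1.24, 6.35 ± 0.41 and 6.20 ± 0.91, none of which passed.

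The porin gene ompF had an mRNA change of -4.67 ± 1.21 and an RPF change of -5.58 ± 1.21, from 4030 to 65.9 RPKM in RPF. In nucleotide metabolism, carB had mRNA and RPF changes of -3.88 ± 0.92 and -3.07 ± 0.92, and pyrB of -3.43 ± 1.05 and -4.03 ± 1.05; all 22 list members were lower in both kinds of library, and 17 passed in mRNA and 11 in RPF when adjusted over the list alone, against 0 and 0 over all tested genes. The uracil salvage and uptake genes upp and uraA had mRNA changes of -4.21 ± 0.33 and -4.09 ± 0.69. For metE, which makes methionine, the mRNA change was -4.35 ± 1.26, and for the arginine-binding protein gene artJ the RPF change was -4.32 ± 0.76; those of ydiY and pyrL were -4.34 ± 0.58 and -3.90 ± 0.72. The zinc uptake genes yodA (zinT) and znuA had mRNA changes of -5.67 ± 0.68 and -4.48 ± 0.64, and the formate metabolism genes hycA and hydN of -4.56 ± 1.15 and -4.05 ± 0.82. The respiratory chain list fell by 1.86 ± 0.47 in mRNA, with 23 of 29 genes past the test adjusted over the list alone and 0 over all tested genes; its RPF change was -0.68 ± 0.47 and did not pass (adjusted p = 0.326). The mRNA call was kept in 6 of 13 settings. With the batch term the change was -1.86 ± 0.79 (adjusted p = 0.221), with the authors' scaling -1.82 ± 0.44 (0.0537) and without the genes of the stretch, where the list has 0 members, -1.86 ± 0.34 (0.0819).

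By limma, 0 genes passed in mRNA, with 479 at an unadjusted p under 0.05 and 0 calls by voom. In RPF 2 passed, voom called 19, a fit on the RPF libraries alone 6, and no rescaling and the batch term 0 each. Leaving out each LB library in turn gave 0 to 7, above 0 only without LB mRNA replicate 2. With the batch term only the RpoS call was kept in RPF, and the osmolyte transport, cold shock and purine and pyrimidine calls were lost (adjusted p = 0.0857 each). Their changes stayed at 2.09, 2.16 and -2.14, since MM and osmotic stress are on the same side of the split, while the SE became 0.79. The purine and pyrimidine call was also lost in mRNA with the authors' scaling (adjusted p = 0.0537), in RPF at a mean RPKM of at least 20 (0.0651) and with quantile normalization (0.0505), and in both without the genes of the stretch (0.0819 and 0.0761). Its changes there ran from -2.56 to -2.67 in mRNA and from -2.05 to -2.09 in RPF. The respiratory chain call in mRNA and the acid resistance (1.70 ± 0.47) and amino acid biosynthesis calls in RPF were lost without any 1 of the 4 LB libraries, with adjusted p from 0.0624 to 0.0929. The changes then ran from -1.83 to -1.86, 1.68 to 1.70 and -1.73 to -1.75, at SEs of 0.65 to 0.67. With the batch term the acid resistance and amino acid biosynthesis changes were 1.70 ± 0.79 and -1.74 ± 0.79 (adjusted p = 0.17 each), and with no rescaling the acid resistance change was 1.36 ± 0.48 (0.0708). The argF-lac list, with 5 of its 28 genes tested, rose by 2.61 ± 0.64 in mRNA. This call was lost without the filter on low values (0.45 ± 0.65, adjusted p = 0.606). With the change still 2.61, it was also lost with the authors' scaling (0.0827) and without the genes of the stretch (0.0824). These genes are deleted in the strain. Their mean level was 7.01 in the osmotic stress mRNA library, 4.41 in MM mRNA, and 3.92 and 3.12 in LB mRNA, and this rise was not examined further. The reads of the region described with the results to look at again follow another pattern, higher in LB replicate 1 and heat stress.

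Ribosome occupancy relative to mRNA was compared between osmotic stress and MM as the difference of the RPF and mRNA changes. It rose for the acid resistance list by 3.12 ± 0.67 (adjusted p = 0.00861) and for the cold shock list by 3.36 ± 0.66 (adjusted p = 0.00855), with all 10 and all 7 genes higher. When the RPF and mRNA values of each LB culture were subtracted first, so that the culture is a block, the changes were the same, but the SE, pooled over all lists, was 1.12, and neither passed (adjusted p = 0.0811 and 0.0744). The batch term gives the same values here, as it leaves the same residual, and is not a separate test. In the acid resistance list, mRNA differed by -1.43 ± 0.47, which did not pass, while RPF rose by 1.70 ± 0.47. The acid chaperone gene hdeA went from 6900 to 1950 RPKM in mRNA and from 12200 to 35900 RPKM in RPF, and its change in RPF relative to mRNA was 3.82 ± 0.94. For hdeD this change was 4.35 ± 0.78, and for gadA, a glutamate decarboxylase gene whose reads cannot be told apart with certainty from those of its near-identical copy gadB, it was 3.88 ± 1.88. For the cold shock list the MM value itself was low: MM against LB, the change in RPF relative to mRNA was -1.98 ± 0.57, which did not pass (adjusted p = 0.127), against 0.00 ± 0.58 for acid resistance. In the cold shock list, cspA went from 6830 to 1980 RPKM in mRNA and from 1080 to 8140 in RPF, a relative change of 5.13 ± 1.01, with cspG at 6.36 ± 1.96 and cspB at 6.01 ± 1.08. Adjusted over the list alone, 5 acid resistance and 4 cold shock genes passed; over all tested genes limma called 0, with 159 at an unadjusted p under 0.05, and voom called 0. For the argF-lac list, with 5 of 28 genes tested and all of them deleted in the strain, the value was -3.66 ± 0.90. Its call was kept in 7 of 13 settings, and with no filter on low values the change was -0.59 (adjusted p = 0.963), so no change is claimed. Other large values that did not pass were those of yodA (5.64 ± 0.96), ygaW (4.76 ± 1.50), ybdL (-5.54 ± 1.02), metB (-4.95 ± 1.25) and metR (-4.52 ± 0.99). For heat stress against LB and for MM against LB, limma called 0 genes and 0 lists in RPF relative to mRNA, with 65 and 72 genes at an unadjusted p under 0.05 and 0 and 0 gene calls by voom. Of 3938 genes, 65, 72 and the 159 for osmotic stress are each a share below 0.05, the share expected with no change. The p-values for RPF relative to mRNA are therefore cautious. No simulation was made for these contrasts, so 0 calls do not show that translation was unchanged. The largest values of RPF relative to mRNA were those of yjdK (ghoS), 4.55 ± 1.64, and treB, -3.28 ± 3.37, for heat stress and of aaeX, 3.63 ± 2.68, and yodA, -6.87 ± 0.83, for MM. Both yjdK and treB lie in the stretch that differed between the LB cultures.

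Across genes, RPF changes followed mRNA changes with a Pearson's r of 0.817 for heat stress (Spearman's rho 0.787), 0.827 for MM (rho 0.749) and 0.526 for osmotic stress (rho 0.465). These correlations are across genes, which are not independent replicates, and the differences between them were not tested. Of the 1336 genes with an mRNA change of at least 2-fold under heat stress, 956 changed at least 2-fold in the same direction in RPF and 12 in the opposite direction. Under osmotic stress these numbers were 435 and 50 of 1048, and in MM 942 and 26 of 1376.

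**Figure D3:**
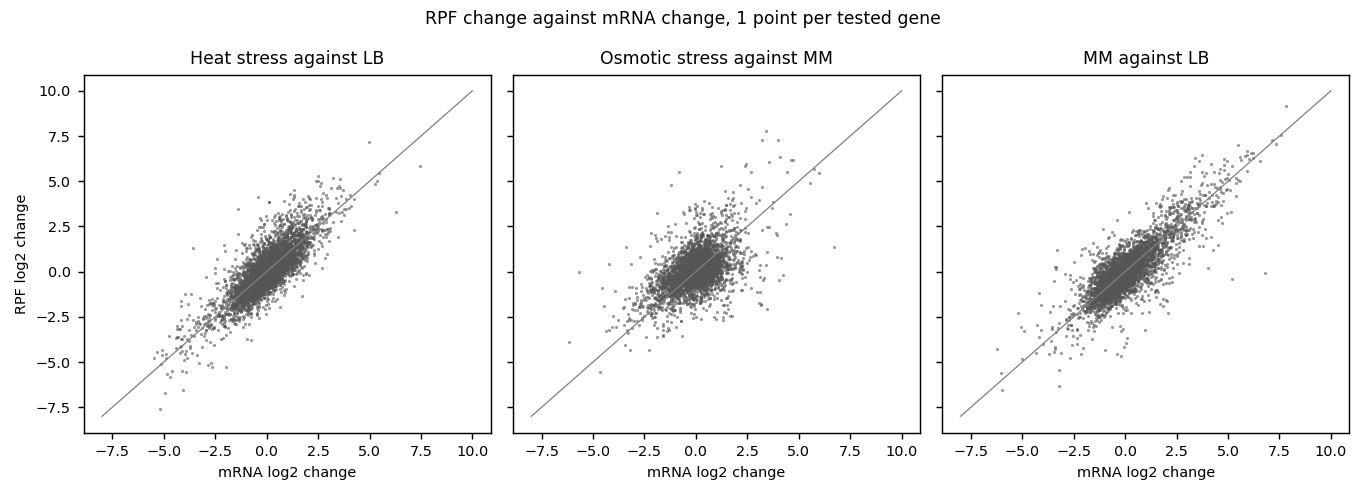
Log2 change in RPF (y axis) against log2 change in mRNA (x axis) for each of the 3938 tested genes, in heat stress against LB, osmotic stress against MM and MM against LB; the line marks equal changes. Pearson's r across genes was 0.817, 0.526 and 0.827.

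Cells in MM carried far more mRNA and RPF of acid resistance and of biosynthesis than cells in LB. The acid resistance list rose by 5.37 ± 0.41 in both mRNA and RPF, sulfate assimilation by 4.83 ± 0.73 and 4.62 ± 0.73 (adjusted p = 0.000228 and 0.000337), amino acid biosynthesis by 2.98 ± 0.42 and 3.65 ± 0.42, and the RpoS list by 2.99 ± 0.42 and 2.83 ± 0.42 (adjusted p = 0.000175 and 0.000274). All members of the acid resistance, sulfate assimilation and RpoS lists were higher in both. Purine and pyrimidine biosynthesis rose by 1.64 ± 0.48 and 2.64 ± 0.48. Ribosomal proteins fell (-1.52 ± 0.42 in mRNA, -1.74 ± 0.42 in RPF), with all 54 genes lower in both. Cold shock proteins fell by 2.19 ± 0.40 in RPF, while their mRNA differed by -0.21 ± 0.40.

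The glutamate decarboxylase gene gadB rose by 7.60 ± 0.40 in mRNA, from 8.22 and 5.54 RPKM in LB to 2440 in MM, with the same limit as gadA; the acid chaperone genes hdeA and hdeB rose by 5.93 ± 0.57 and 5.91 ± 0.65. Adjusted over the list alone, 10 of 10 acid resistance genes passed in mRNA and in RPF, against 5 and 6 over all tested genes. The leucine biosynthesis genes leuB, leuC and leuD rose by 7.32 ± 0.45, 7.13 ± 0.39 and 6.58 ± 0.55 in mRNA. In RPF, gadB, leuC and leuB rose by 7.53 ± 0.40, 7.30 ± 0.39 and 7.08 ± 0.45, metE rose by 9.15 ± 1.09, to 23500 RPKM from 14.0 and 60.7 in LB, and ilvC, of branched-chain amino acid synthesis, by 7.00 ± 0.74. Of the 73 amino acid biosynthesis genes, 52 passed in mRNA and 63 in RPF when adjusted over the list alone, against 15 and 36 over all tested genes. In sulfate assimilation, cysN and cysD were higher in mRNA by 5.94 ± 0.82 and 5.63 ± 1.17; 10 of 11 genes passed in mRNA and in RPF adjusted over the list alone, and 0 over all tested genes. The ribosome hibernation factor gene rmf rose by 6.24 ± 0.48 and yodA (zinT) by 6.81 ± 0.59 in mRNA. In the RpoS list, osmC and yiaG rose by 4.18 ± 0.43 and 4.29 ± 0.30 in mRNA and katE, a catalase gene, by 4.91 ± 0.54 in RPF; 27 of 29 genes passed in mRNA and 24 in RPF adjusted over the list alone, against 3 and 11.

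Serine degradation and transport genes were among the largest falls: sdaB and sdaC changed by -6.06 ± 0.34 and -5.97 ± 0.41 in mRNA and by -5.61 ± 0.34 and -6.55 ± 0.41 in RPF. The formate dehydrogenase genes fdoH, fdoI and fdhE changed by -5.03 ± 0.33, -4.01 ± 0.33 and -3.19 ± 0.35 in mRNA, and proX by -3.40 ± 0.37. In RPF, fdoH changed by -4.86 ± 0.33, proV by -4.51 ± 0.48 and yqeG by -4.43 ± 0.49. The glycerol uptake genes glpT and glpK had mRNA changes of -6.25 ± 2.08 and -5.20 ± 1.40, which did not pass. Of the 54 ribosomal protein genes, 52 passed as lower in mRNA and 51 in RPF when adjusted over the list alone, against 0 and 3 over all tested genes; rpsS and rpsQ had mRNA changes of -2.00 ± 0.36 and -1.94 ± 0.34. The cold shock genes cspG and cspA had RPF changes of -4.66 ± 1.20 and -4.34 ± 0.62. The respiratory chain list fell (-1.42 ± 0.41 in mRNA, -1.54 ± 0.41 in RPF), as did uptake of other carbon sources (-1.78 ± 0.62 and -2.20 ± 0.62).

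In mRNA 42 genes passed, 36 higher and 6 lower, and in RPF 107, 91 higher and 16 lower; with no rescaling the counts were 183, 176 higher and 7 lower, and 162, 150 higher and 12 lower. Voom called 110 and 289, a pseudocount of 5 gave 139 and 185, the fit without the genes of the stretch 157 and 279, a fit on one kind of library 0 and 201, and the batch term 0 and 0. Quantile normalization gave 101 in mRNA. Leaving out LB mRNA replicate 1 or either LB RPF library gave 0 calls in both, and leaving out LB mRNA replicate 2 gave 91 and 202, so the number of calls depends on which LB libraries enter. Without LB mRNA replicate 2 the purine and pyrimidine call in mRNA was lost (1.12 ± 0.67, adjusted p = 0.293), and the ribosomal protein call was lost without either LB mRNA library (adjusted p up to 0.141) and, in RPF, without LB RPF replicate 1 (0.0663). The respiratory chain call was lost in mRNA without any 1 of the 4 LB libraries (adjusted p up to 0.184) and in RPF without either LB RPF library (up to 0.0707), and the carbon uptake call without LB mRNA replicate 1 in mRNA (0.133) and without LB RPF replicate 2 in RPF (0.0943). Leaving out an LB library moved the carbon uptake change to between -2.12 and -1.47 in mRNA and between -3.03 and -1.39 in RPF, so its size depends on the LB library used. The carbon uptake call was kept in 5 of 13 settings in mRNA and in 8 of 13 in RPF. Of its 32 genes, 8 lie in the stretch that differed between the LB cultures. Without them the changes were -1.70 ± 0.78 and -1.58 ± 0.78 and did not pass (adjusted p = 0.232 and 0.193). With no rescaling the changes of the list were -1.08 ± 0.66 and -1.75 ± 0.66 (adjusted p = 0.239 and 0.0551). With the batch term the ribosomal protein calls (-1.46 and -1.68, adjusted p = 0.208 and 0.0869), the respiratory chain calls (-1.36 and -1.48, 0.208 and 0.137) and the mRNA calls of purine and pyrimidine biosynthesis (1.91, 0.0648) and of carbon uptake (-2.04, 0.0531) were lost, each with an SE of 0.74. The purine and pyrimidine call in mRNA was also lost with the authors' scaling (1.29 ± 0.51, adjusted p = 0.103), at a mean RPKM of at least 20 (1.59 ± 0.52, 0.0765), with quantile normalization (1.59 ± 0.49, 0.0815) and without the genes of the stretch (1.73 ± 0.51, 0.0677). The scaling moved the changes themselves. With no rescaling and with quantile normalization the ribosomal protein change in mRNA was -0.82 and -0.20 and did not pass (adjusted p = 0.176 and 0.676), and with quantile normalization that in RPF was -0.59 (0.144). With no rescaling the respiratory chain change was -0.72 in mRNA (adjusted p = 0.239) and -1.09 in RPF (0.0616).

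**Figure D4:**
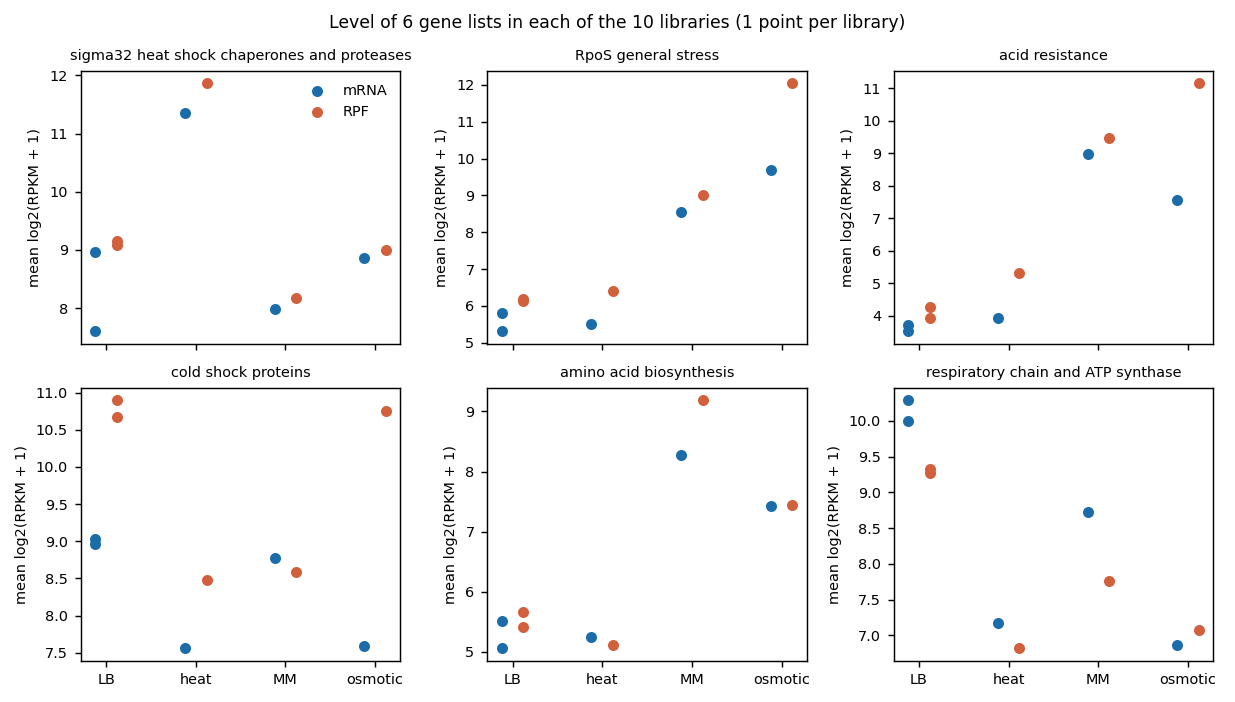
Mean log2(RPKM + 1) of 6 gene lists in each library, with mRNA in blue and RPF in orange and 1 point per library. The acid resistance list was higher by 5.37 in MM than in LB in both kinds of library; against MM, osmotic stress differed by -1.43 in mRNA and by 1.70 in RPF.

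The heat and osmotic responses were set against each other, which is the question of the series title. These comparisons share no library. In RPF, the heat response was below the osmotic response by a log2 difference of -4.47 ± 0.62 for the cold shock list (adjusted p = 0.000417, all 7 genes) and of -2.80 ± 0.64 for the RpoS list (adjusted p = 0.0140, 28 of 29 genes). The mean RPF level of the cold shock list, as log2(RPKM + 1), was 10.90 and 10.67 in LB, 8.48 under heat stress, 8.59 in MM and 10.75 under osmotic stress, so the osmotic rise runs from 1 low MM library to about the LB level. The cold shock list fell by 2.31 under heat stress and rose by 2.16 under osmotic stress, and the RpoS list differed by 0.24 ± 0.42 under heat stress against 3.04 ± 0.49. Of the named genes, yjbJ, cspG and cspB had RPF differences of -6.80 ± 0.43, -7.18 ± 1.83 and -6.14 ± 1.01, and ibpB of 6.03 ± 0.65. The sigma32 list had a difference of 2.18 ± 0.82 in mRNA and 1.92 ± 0.82 in RPF, neither of which passed (adjusted p = 0.211 and 0.124). By limma 0 genes passed in mRNA and 0 in RPF, with 238 and 487 at an unadjusted p under 0.05 and 0 and 0 by voom, and 0 lists passed in mRNA, with 4 at an unadjusted p under 0.05. The RpoS difference was lost at a mean RPKM of at least 20, with no rescaling, with quantile normalization, with the batch term and without the genes of the stretch, with changes from -2.43 to -2.94 and adjusted p up to 0.144.

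Across genes, the heat and osmotic changes had a Pearson's r of 0.427 in mRNA (Spearman's rho 0.444) and 0.267 in RPF (rho 0.277). Of the genes at least 2-fold higher in mRNA, 722 under heat stress and 477 under osmotic stress, 238 were shared, where independent lists would share 87.5; of those at least 2-fold lower, 222 were shared against 89.0. In RPF, 201 were shared among the higher genes against 128.7, and 181 among the lower genes against 88.8. The respiratory genes cyoA and cyoB were in the shared set of lower mRNAs, with changes of -5.50 and -5.08 under heat stress and -2.42 ± 0.34 and -2.59 ± 0.38 under osmotic stress.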

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

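The tests of growth medium, of gene dosage, of copy number, of background and of an intact region in the first paragraphs, and the test of lost RNA in the last, were chosen only after the result was seen; those of shared copies, gene length and scaling were written before.

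In RPF, the responses to heat and osmotic stress differed for the RpoS list by -2.80 and for the cold shock list by -4.47, in a test of the difference itself, which put both lists here. The cold shock difference also rests on 1 low MM library, with a mean level of 8.59 against 10.90 and 10.67 in LB and 10.75 under osmotic stress.

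Reads in the argF-lac region, which the strain lacks, were higher in LB replicate 1 and heat stress, 4 libraries, than in the other 6 by a median log2 difference of 1.05 over the 95 listed genes from ykfI to mhpC (quartiles 0.66 and 1.33), though the region held at most 0.0841% of the reads of a library. For reads shared with copies elsewhere, 28.4% of the genes were higher in each of the 4 libraries than in each of the other 6. That is under the 50% set beforehand, which leaves the explanation standing. The share cannot decide, since at a median of 3.56 RPKM few reads alone can lower it. The rise was not limited to a few genes, with a lower quartile of 0.66, which copies of a few genes alone would not give. The genes lacZ (1.99), lacY (1.06), lacI (1.14) and cynT (1.34) had higher means too. A later count, 95.8% of genes with a higher mean, decides nothing, as the quartiles fix it. A higher background at all weakly expressed genes remains a candidate explanation, since 20 genes elsewhere matched on level to each gene of the region were higher in the same libraries by a median of 0.79; a first test on the flagella list gave 0.25, which would argue against it, but that list lies at a higher level (median 6.22 against 3.56 RPKM). Cells or DNA with an intact region may add to it: the excess over the matched genes was 0.35 (95% bootstrap interval 0.19 to 0.41), too small for the 1 set as the bound. The interval resamples genes, which are not independent, and holds no spread between libraries, so it does not show that the excess is above 0. An intact region cannot be told apart from background.

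Most of the 372 genes from metA to yjtD were lower in LB replicate 1 and heat stress than in LB replicate 2, MM and osmotic stress. This does not say which libraries depart. The tenth percentile of the stretch was 0.634 to 0.874 times that of the other tested genes in the LB replicate 1 and heat stress libraries. In the LB replicate 2, MM and osmotic stress libraries it was 1.9 to 4.09 times as high, so there the weakest genes of the stretch stood above those elsewhere. LB replicate 2 was above replicate 1 at 89.5% of them in mRNA and 88.2% in RPF. The mean of MM and osmotic stress was above heat stress at 75.8% and 69.9%, by a median of 0.91 and 0.76. The ends of the stretch were set from the mRNA differences between the LB cultures. The RPF difference between the same cultures, 1.24 relative to the other genes, could therefore hardly fail and is no separate test of growth medium or stress. As these cultures share the medium, medium does not account for the difference between them. Gene dosage around the replication origin is argued against by the stretch at the same distance on the other arm, which differed by 0.10 in RPF. A different copy number of the stretch may account for it and cannot be told apart from other explanations. The weakly and strongly expressed genes differed by 0.80 in their median shift, where 1 ratio of copies predicts under 0.5. The 95% bootstrap interval, 0.38 to 1.01, spans that bound. It resamples genes, which are not independent, and holds no spread between cultures.

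The rise of RPF relative to mRNA for acid resistance and cold shock genes in osmotic stress has 1 library of each kind in each condition, and for cold shock the MM value itself differed from LB by -1.98, which did not pass. Gene length is argued against by genes of the nearest length, whose median change was 0.33 against 3.58 for the members, and scaling by the smallest change under 4 scalings, 2.68. Loss of RNA from the osmotic stress mRNA library cannot be told apart from a change in translation. The mRNA changes were -1.43 and -1.20, and a fall in mRNA is what loss predicts. Both RPF changes, of which the smaller was 1.70, were above 1, the bound set against loss. Both were also below the 3.04 of the RpoS list, the bound set for loss. These RPF bounds cannot decide, since loss from an mRNA library predicts no value of RPF. With the culture as a block the changes stayed at 3.12 and 3.36, but their SE went from 0.67 and 0.66 to 1.12, pooled over all lists, and neither passed (adjusted p = 0.0811 and 0.0744).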

How the results depend on the processing

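No test in this part was chosen as an explanation after the result was seen; limma-voom, the authors' scaling, the batch term (LB replicate 1 and heat stress against the rest) and the fit without the genes of the stretch were added after seeing the data.

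Of 176 counts of genes, 132 stayed within 1.5 times, and of 146 counts of lists, 118. A count of 0 that stayed 0 is included. The main fit called 0 genes in most contrasts, so the share for genes says little on the contrasts with calls. Of 3960 list means, 3542 stayed the same, 125 lost the call, 31 gained it, 262 moved (a mean with no call that changed sign, or, where no test was made without an LB culture, a shift beyond the SE), and 0 called means reversed. Here and for the named genes, a tested value stayed the same if its sign and its call, or lack of a call, were kept. Its size could change: the sulfate assimilation change in mRNA in MM ran from 3.84 to 5.8. Most list means had no call to lose, so the 125 lost calls are to be set against the called means only. Of 4250 values of genes named in the text, 3930 stayed the same, 192 lost the call, 122 gained it, 6 without a call changed sign and 0 reversed. Under every alternative of the list test, the calls of sigma32 and respiratory genes under heat stress (mRNA and RPF), of RpoS genes under osmotic stress (RPF) and of acid resistance, sulfate assimilation, amino acid biosynthesis and RpoS genes in MM (mRNA and RPF) were kept. For osmotic stress against MM, a kept call or mean says less. That contrast holds no LB library, so leaving one out kept the RpoS change in RPF at 3.03 to 3.05. The batch term could likewise alter only the SE there. No alternative tests the single libraries of heat stress, MM and osmotic stress. Where a result moved, the cause was not tested. With an LB library left out, the lone LB library is assumed to vary like the other pair. With 2592561 to 7759736 reads per library, weakly expressed genes have few reads.

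Genes called for heat stress in mRNA (0) were 2 with a pseudocount of 5, 18 with no filter, 11 with quantile normalization, 10 with the authors' scaling, 47 without the stretch and 0 to 8 leaving out a library. For heat stress in RPF (7) they were 0 with a pseudocount of 5, 1 with no rescaling, 3 with quantile normalization, 0 with the batch term, 165 without the stretch and 0 to 14 leaving out a library. For osmotic stress in RPF (2) they were 0 with no rescaling, 19 by voom, 0 with the batch term, 6 with RPF alone and 0 to 7 leaving out a library. For MM in mRNA (42) they were 139 with a pseudocount of 5, 183 with no rescaling, 101 with quantile normalization, 110 by voom, 0 with the batch term, 157 without the stretch, 0 with mRNA alone and 0 to 91 leaving out a library. For MM in RPF (107) they were 185 with a pseudocount of 5, 162 with no rescaling, 289 by voom, 0 with the batch term, 279 without the stretch, 201 with RPF alone and 0 to 202 leaving out a library.

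Lists called for heat stress in mRNA (7) were 3 at a mean RPKM of at least 20, 4 with quantile normalization, 4 with the batch term and 4 to 5 leaving out a library. For heat stress in RPF (8) they were 5 with the batch term, 5 without the stretch and 5 to 6 leaving out a library. For osmotic stress in mRNA (3) they were 5 with a pseudocount of 5, 8 with quantile normalization, 0 with the authors' scaling and 0 without the stretch, and in RPF (6) 1 with the batch term. For MM in mRNA (8) they were 5 with no rescaling, 5 with quantile normalization, 4 with the batch term and 5 to 7 leaving out a library. For the heat against the osmotic response in RPF (2) they were 7 with a pseudocount of 5, 1 at a mean RPKM of at least 20, 1 with no rescaling, 1 with quantile normalization, 1 with the batch term, 1 without the stretch and 3 to 4 leaving out a library.

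For RPF relative to mRNA under osmotic stress, 3 lists passed and 0 in the replicate block fit, where the RPF and mRNA libraries of an LB culture are subtracted first (adjusted p = 0.0811 for acid resistance, 0.0744 for cold shock). The batch term gives the same fit for this result. The changes were the same and the SE was 1.12.

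The correlation of mRNA and RPF changes for osmotic stress (0.526) was 0.560 with a pseudocount of 5 and 0.574 at a mean RPKM of at least 20. Leaving out an LB culture, it was 0.686 to 0.764 for heat stress (0.817) and 0.723 to 0.790 for MM (0.827). The correlation of heat and osmotic changes in mRNA (0.427) was 0.406 at a mean RPKM of at least 20, 0.461 without the stretch and 0.368 to 0.395 leaving out an LB culture, and in RPF (0.267) it was 0.297 with a pseudocount of 5, 0.315 at a mean RPKM of at least 20 and 0.235 to 0.266 leaving out an LB culture.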

Other observations

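No test in this part was planned with a prediction; its values are descriptions.

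Lists with no call in mRNA or RPF in any of the 3 comparisons include envelope stress, phage shock, iron uptake, flagella, oxidative stress, SOS response, translation factors, and amino acid and peptide uptake. Under heat stress the mRNA and RPF means were 0.23 and -0.04 for sigmaE envelope stress, 0.12 and 0.64 for Cpx envelope stress, -0.06 and 0.01 for phage shock, -1.03 and -0.96 for iron uptake, 0.12 and 0.35 for flagella and chemotaxis, -0.71 and -0.67 for oxidative stress, 0.25 and -0.21 for the SOS response, -0.72 and -0.43 for translation factors, and 0.03 and 0.24 for amino acid and peptide uptake. Under osmotic stress 34 of the 40 iron uptake genes were higher in RPF, with a mean of 1.63 ± 0.64 that did not pass (adjusted p = 0.0962), and the enterobactin genes entB and entC were higher by 3.43 ± 0.91 and 3.31 ± 0.68. All 7 phage shock genes were higher in mRNA, with a mean of 1.41 ± 0.48 (adjusted p = 0.0643).

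The zinc-binding protein gene yodA (zinT) stood at 1590 RPKM in the MM mRNA library and at 18.5 RPKM in the MM RPF library, and at 7.65 to 32.6 RPKM in the other mRNA libraries. The zinc uptake gene znuA stood at 2610 and 199 RPKM in the same libraries. The ribosome hibernation factor gene rmf, which rose in MM, stood at 22900 RPKM in the osmotic stress RPF library against 2160 in MM. These 3 genes were chosen after their values were seen.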
